A study of Homo sapiens with 3 samples.

How the data were processed

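The samples were 3 untreated preparations of iCell GlutaNeurons (called iGluta), a commercial line of human glutamatergic neurons differentiated from induced pluripotent stem cells and sold by FujiFilm Cellular Dynamics. They had been kept in culture for 3 weeks. Per the labels' protocols, column-purified total RNA was treated with DNase, polyadenylated RNA was selected, and strand-specific libraries were sequenced on an Illumina NovaSeq as paired reads of 151 bp. Selection for polyadenylated RNA leaves out transcripts without a tail. The protocol named no molecular identifiers, and whether PCR copies were removed in another way is not given in the sources used here. The labels describe triplicate samples and do not say that they came from separate cultures. Every error and p-value therefore measures the spread between these 3 samples, which may be technical.

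The authors deposited a table of estimated counts and a table of TPM (length-corrected transcript shares scaled to a fixed total), each with 78932 genes and a column per sample. Per the submitters' processing notes, RSEM (version not given) and the genome build GRCh38.p14 were used. The aligner, the annotation release, any filters and the strand setting of the counting are not given in the sources used here. The deposited estimated counts were not all whole numbers, because RSEM divides reads that match several genes. Of all 78932 values, zeros included, 13.9, 15.4 and 13.4% were not whole in replicates 1, 2 and 3. Only 31802, 34966 and 31079 genes had any count in the same order, so the share among counted genes was higher. Genes with near-identical copies or overlapping neighbours are therefore less certain than others. The deposited TPM values summed to the same total in each library, so each value is a share: a transcript that takes a larger share lowers all others. TPM also divides by the effective transcript length, which makes the values of very short transcripts uncertain.

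The libraries held 41079348, 60092991 and 34732725 estimated counts in replicates 1, 2 and 3. A count of 0 allowed up to 3 counts, which is 0.073, 0.05 and 0.086 CPM (counts scaled by the library total) in the same order, and these floors cover counting error only. Replicate numbers were taken from the sample titles. A chi-square comparison of the counts gave 25.1 per degree of freedom for replicates 1 and 2, 50.2 for 1 and 3 and 71.3 for 2 and 3, so no library had been deposited in duplicate, and all 3 were used.

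The series has 1 group, so no test between groups was possible, and levels were compared with a fixed bar and with each other within a library. Levels are given as mean TPM ± SD over the 3 libraries, and genes are ordered by TPM, an order that can differ on counts. Each gene's mean was compared with a bar of 1 TPM using limma 3.58.1 (intercept-only fit, eBayes with trend, 2-sided) on log2(TPM + 0.1), with Benjamini-Hochberg adjustment over the 38992 genes with any TPM above 0. A gene was called above or below the bar at an adjusted p under 0.05 and was otherwise undecided. On this scale differences of low genes are understated. The step was tested on simulated data for 36830 genes. All 40 genes set at 4 TPM and 32 of 40 set at 2 TPM were called above, none of 40 set at 1 TPM was called, and 33 of 40 set at 0.5 TPM were called below.

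Cell types, transmitter systems, regional identity, receptors, channels and cell state were described with 44 gene lists (411 genes) written before the data were examined. Another 14 ratios between genes and 4 differences between list medians were fixed at the same time. Each was computed within every library as a log2 value with a pseudocount of 0.1, and its mean was tested with an exact 2-sided sign-flip permutation test, whose smallest possible p with 3 libraries is 0.25. No ratio could therefore pass a threshold of 0.05. A ratio was called different from 0 when all 3 libraries had the same sign and the mean was over 2 SD from 0. The spread between the samples was estimated with edgeR 4.0.16 on the counts, rounded to whole numbers (TMM scaling, filterByExpr, 19089 genes), as the common biological coefficient of variation. How far a list stood apart in a library was described by the median log2 difference of its members (mean TPM of at least 1) from the mean of the other libraries. That median was placed among 10000 random lists matched on expression.

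Genes to be named were the 4 highest members of each list (all members of lists of 5 or fewer), every gene of the ratios and the 15 highest genes of the table, 206 genes in all. Some of these genes, and 2 of the ratios, are not reported here, and the plots show only genes named in the text. Genes named outside that rule are said to have been chosen after their values were seen. Gene positions come from a RefSeq table on GRCh38.p14, the build of the files, which matched 461 of the 475 genes described by symbol. GC content and transcript length came from GENCODE release 29. The alternatives tried were DESeq2 1.42.0 size factors, no filter on low counts, bars of 0.5 and 2 TPM, pseudocounts of 0.01 and 1, a mean count of at least 10, TMM-rescaled TPM, CPM in place of TPM, eBayes without trend, list means in place of medians, and leaving out each replicate. R 4.3.3 and Python 3.11.15 were used.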

Results

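RNA was measured in 3 untreated samples of iGluta neurons after 3 weeks of culture, in order to describe which cell types the culture held and which receptors and channels it expressed. The libraries held 41079348, 60092991 and 34732725 estimated counts in replicates 1, 2 and 3. Values below are mean TPM ± SD with n = 3 unless a library is named. Of 38992 genes with any signal, 15837 were above 1 TPM, among them 12668 protein-coding genes and 2709 long noncoding RNAs, and 17574 were below it (limma, adjusted p under 0.05). The remaining 5581 were undecided.

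The most abundant nuclear transcripts were TMSB10 (8418 ± 571 TPM), which encodes an actin-binding thymosin, the tubulin gene TUBA1A (7299 ± 897) and the G protein gene GNAS (6464 ± 546). Of the 15 highest genes, 8 were mitochondrial, and their levels differed between libraries. MT-ATP8 was at 4263, 4561 and 16262 TPM and MT-CO2 at 4330, 3980 and 12013 in replicates 1, 2 and 3, so replicate 3 sets their high means. Mitochondrial mRNA made up 3.52, 3.35 and 9.63% of TPM. The common biological coefficient of variation was 0.188 over 19089 genes (edgeR), and it was 0.12 without replicate 3, 0.218 without replicate 1 and 0.211 without replicate 2. TMSB10, FTH1, EEF1A1, ACTB and ACTG1 have many processed pseudogenes, and mitochondrial genes have copies in nuclear DNA, so the reads given to them are less certain.

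The first question was the cellular composition. All 18 pan-neuronal genes were above 1 TPM. The highest were STMN2 (2449 ± 327 TPM), a regulator of microtubules in growing neurites, UCHL1 (2101.5 ± 111), a neuronal ubiquitin hydrolase, GAP43 (1740.1 ± 73.9), a growth cone protein, and TUBB3 (1592 ± 225), the neuronal tubulin. The largest adjusted p of the 18 was 3.29e-09 (NEFH, limma; chosen after its value was seen), and 18 were also above when adjusted over the list alone. DCX, a microtubule protein of immature neurons, stood at 250.2 ± 45.7 TPM against 81.2 ± 2.13 for RBFOX3, the gene of the mature marker NeuN. Their log2 ratio was 1.61 ± 0.29, positive in 3 of 3 libraries (exact sign-flip permutation p = 0.25, the smallest possible), and 3.73 on CPM, which is not divided by gene length.

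Markers of glia and vessel cells were mostly low. The median of the pan-neuronal list exceeded that of the astrocyte list by 8.47 ± 0.33 on the log2 scale (8.11, 8.73 and 8.58 in replicates 1, 2 and 3; exact permutation p = 0.25), and by 9.76 on CPM. Of 12 astrocyte genes 5 were above 1 TPM, led by the glutamate transporter SLC1A2 (61.6 ± 17.1 TPM) and the glycolytic enzyme gene ALDOC (61.1 ± 15.3), followed by S100B (2.11 ± 0.464) and CD44 (2.05 ± 0.251). GFAP, the filament of astrocytes (0.823 ± 0.032 TPM), and the water channel AQP4 (0.84 ± 0.0361) were undecided; both were chosen after their values were seen. In the oligodendrocyte list 2 of 10 were above, CNP (74.9 ± 6.84 TPM) and MBP (42.7 ± 5.57), while SOX10 (0.437 ± 0.415) was undecided. None of 11 microglial genes was above 1 TPM at an adjusted or an unadjusted p under 0.05 (limma), and the highest was CSF1R at 0.68 ± 0.322 TPM. None of 6 endothelial genes was above either, with 0 at an unadjusted p under 0.05 (limma) and VWF the highest at 0.44 ± 0.396 TPM. With each replicate left out, 2 to 3 of the astrocyte genes were above the bar (2 without replicate 1, 3 without replicate 2 or 3).

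**Figure D1:**
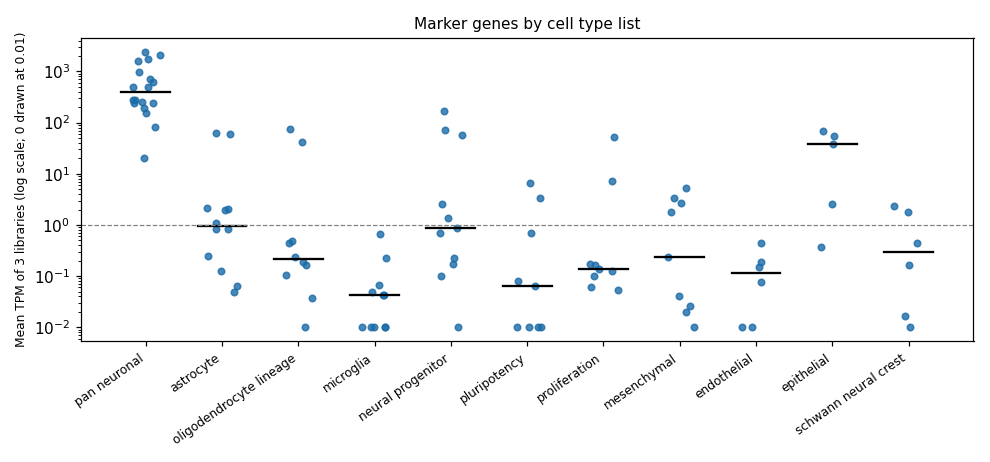
Mean TPM over 3 libraries (vertical log axis, 0 drawn at 0.01) of each gene of 11 cell type lists, 1 point per gene, with a black bar at the list median and a dashed line at 1 TPM. The pan-neuronal median is 389 TPM, the astrocyte median is 0.973 and the microglial median is 0.0433.

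Genes of dividing and undifferentiated cells were also low, with exceptions. In the progenitor list 3 of 11 were above 1 TPM: the filament genes VIM (170.0 ± 83.8 TPM) and NES (56.8 ± 27.6) and the transcription factor PAX6 (72.3 ± 22.1). VIM was at 123, 119.8 and 267 TPM and NES at 38.0, 43.9 and 88.5 in replicates 1, 2 and 3, while PAX6 ran the other way at 84.5, 85.5 and 46.8. Of 9 proliferation genes PCNA (52.4 ± 10.3 TPM), which also serves DNA repair, and CCNB1 (7.13 ± 2.61) were above, and 7 were below, including CDK1 (0.17 ± 0.08) and CENPF (0.167 ± 0.0379). Without replicate 2 the list had 1 gene above, PCNA. Of 9 pluripotency genes DNMT3B (6.64 ± 0.905 TPM) and LIN28A (3.32 ± 0.587) were above. The epithelial list had 4 of 5 genes above: KRT18 (67.1 ± 22.8 TPM), KRT8 (55.2 ± 52.0), EPCAM (38.5 ± 5.22) and KRT19 (2.58 ± 0.303). KRT8 stood at 25.9, 24.4 and 115 TPM in replicates 1, 2 and 3. KRT8 and KRT18 overlap in the annotation on chromosome 12 (from 52897191 to 52949860 and from 52948855 to 52952906 in GRCh38.p14) and have many pseudogenes, so their values are less certain. In the mesenchymal list 4 of 9 genes were above, all under 6 TPM on average, led by TAGLN (5.33 ± 0.176) and COL1A2 (3.36 ± 1.45), and 2 without replicate 1 or 2. In the Schwann and neural crest list 1 of 6 was above, ERBB3 (2.36 ± 0.959 TPM), and 0 were above without replicate 1 or 2.

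The next comparison set the transmitter systems against each other. Both the glutamatergic and the GABAergic genes were expressed. Of the glutamatergic list 6 of 10 were above 1 TPM, with SLC17A6, the vesicular transporter VGLUT2, at 115 ± 40.6 TPM, SLC17A7 (VGLUT1) at 13.8 ± 5.3, CAMK2B at 138 ± 2.82 and CAMKV at 132 ± 17.5. SLC17A8 (VGLUT3) was undecided at 0.61 ± 0.455 TPM. SLC17A6 exceeded SLC17A7 by 3.06 ± 0.32 on the log2 scale in 3 of 3 libraries (exact permutation p = 0.25), and by 3.43 on CPM. Of the GABAergic list 11 of 15 were above, with the neuropeptide gene SST at 729.7 ± 379 TPM, the GABA-synthesising enzyme genes GAD1 (185 ± 60.0) and GAD2 (74.3 ± 30.7), the vesicular GABA transporter SLC32A1 (147 ± 53.0) and the calcium-binding protein gene CALB2 (122 ± 37.7). For each of the 44 lists the count above the bar was the same when adjusted over the list alone; only in the oligodendrocyte list did the count below differ, 7 against 5.

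The balance between the 2 systems was not settled by these libraries. The summed vesicular glutamate transporters were at 93.0, 116 and 180.1 TPM in replicates 1, 2 and 3, and the summed GAD genes at 286, 334 and 158. Their log2 ratio was -1.62, -1.52 and 0.19, a mean of -0.99 ± 1.02 (exact permutation p = 0.5), so it was not larger than the spread. Against SLC32A1 the glutamate transporters gave -0.96, -0.59 and 1.06, a mean of -0.16 ± 1.07 (exact permutation p = 1.0). The list medians gave a glutamatergic minus GABAergic difference of -1.19 ± 0.77, negative in 3 of 3 libraries but within 2 SD of 0 (exact permutation p = 0.25). Without replicate 3 the means were -1.57, -0.78 and -1.63 over the other 2 libraries, each more than 2 SD from 0. On CPM they were -0.575, 0.34 and -0.26, each within 2 SD of 0, so the ratio to SLC32A1 turned. With list means the list difference was -1.38, over 2 SD from 0. It turned to 0.24 with members of a mean count of at least 10, which leaves out NEUROD1, NEUROD2, NEUROD6, PVALB and NPY, chosen after their values were seen.

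**Figure D2:**
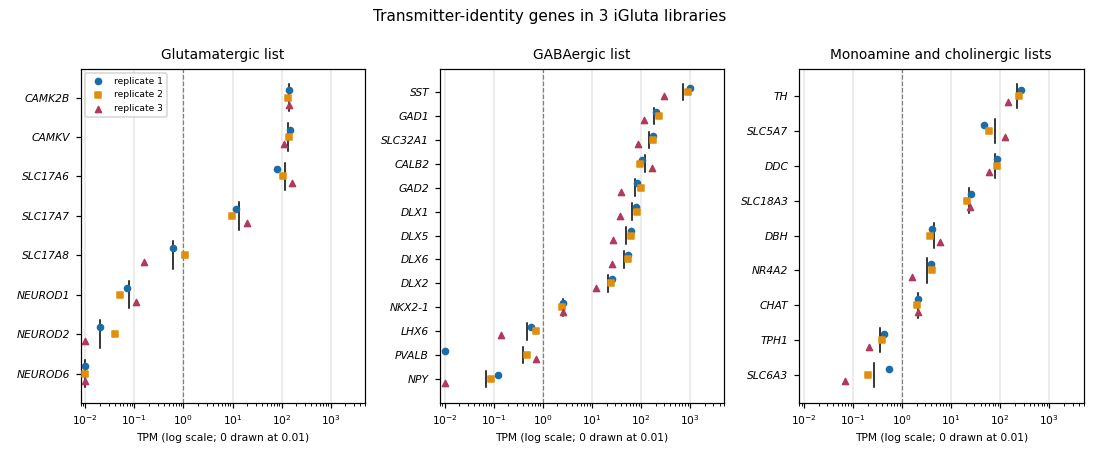
TPM (horizontal log axis, 0 drawn at 0.01) of genes named here from the glutamatergic, GABAergic, and monoamine and cholinergic lists in replicates 1 to 3 (circle, square, triangle), with a black tick at the mean and a dashed line at 1 TPM. SLC32A1 lies at 181, 175 and 86.4 TPM and SLC17A6 at 80.7, 105 and 160.1 TPM in replicates 1, 2 and 3.

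Genes of other transmitters were expressed in part. TH, the rate-limiting enzyme of catecholamine synthesis, was at 219 ± 63.8 TPM and DDC, the next enzyme, at 77.2 ± 16.4. DBH, which makes noradrenaline, was at 4.57 ± 1.13 TPM, and the transcription factor NR4A2 at 3.22 ± 1.39. In that list 5 of 9 genes were above 1 TPM, and 3 without replicate 1 or 2. SLC6A3, the dopamine transporter, was below the bar at 0.273 ± 0.248 TPM and was chosen after its value was seen. All 3 cholinergic genes were above, with the choline transporter SLC5A7 at 47.8, 60.5 and 123.9 TPM in replicates 1, 2 and 3, the vesicular transporter SLC18A3 at 23.4 ± 2.25 and the synthesising enzyme CHAT at 2.08 ± 0.07. SLC18A3 lies inside CHAT on chromosome 10 (from 49610310 to 49612720 within 49609095 to 49667942 in GRCh38.p14), so their reads can be confused. None of 4 serotonergic genes was above (limma, 0 at an unadjusted p under 0.05), with TPH1 the highest at 0.35 ± 0.123 TPM. For glycine, the transporter gene SLC6A9 was above (13.1 ± 2.83 TPM), and SLC6A5, of glycinergic terminals, was below (0.05 ± 0.0436).

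Forebrain genes were expressed, and HOX genes were low or listed at 0. Of the forebrain and cortical list 8 of 14 were above 1 TPM, among them TLE4 (91.9 ± 23.1 TPM), TBR1 (82.5 ± 9.91) and LHX2 (36.7 ± 12.3), transcriptional regulators of the developing telencephalon. Of the hindbrain and spinal list of 12 HOX genes none was above (limma, 0 at an unadjusted p under 0.05). In that list 9 genes, HOXA3 among them, had 0 counts in every library, which allows up to 0.05 to 0.086 CPM per library. The highest HOX gene was HOXA5 at 0.117 ± 0.117 TPM. The forebrain median exceeded the HOX median by 6.35 ± 0.4 on the log2 scale (exact permutation p = 0.25) and by 7.06 on CPM, a difference set largely by the pseudocount because the HOX median is at 0. It exceeded the peripheral sensory median by 2.48 ± 0.44 (exact permutation p = 0.25), by 3.94 on CPM and by 3.3 with members of a mean count of at least 10. In the peripheral sensory list 4 of 9 genes were above, with ISL1 (66.4 ± 10.7 TPM) far ahead of AVIL (3.94 ± 1.24) and PHOX2A (2.17, 1.3 and 3.98 in replicates 1, 2 and 3), and 2 were above without replicate 1 or 2.

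The second question was the expression of receptors and channels. The receptor and channel lists held 215 genes, among them auxiliary subunits, glutamate uptake genes and chloride transporters. Of the 215 genes 161 were above 1 TPM, 29 were below, 22 were undecided and 3 were listed at 0 (limma, adjusted over all genes). Among the ionotropic glutamate receptors all 4 AMPA, all 5 kainate and 6 of 7 NMDA genes were above. The AMPA genes were led by GRIA2 (115 ± 20.7 TPM), whose subunit limits calcium entry, and GRIA1 (90.0 ± 21.0), with GRIA3 at 32.2 ± 4.4 and GRIA4 at 23.2 ± 3.31. The kainate genes were led by GRIK5 (117 ± 3.32 TPM) and GRIK3 (64.6 ± 14.1). The NMDA genes were led by GRIN3A (53.0 ± 5.47 TPM), the obligatory subunit GRIN1 (37.0 ± 1.09) and GRIN2D (29.02 ± 1.73), ahead of GRIN2B (10.7 ± 4.52) and GRIN2A (3.54 ± 1.04), and GRIN2C was undecided at 0.77 ± 0.17. These orders hold on TPM and turn in part on counts, which are not divided by gene length: GRIN2B (6142, 13992 and 4021 counts in replicates 1, 2 and 3) exceeded GRIN1 (2780, 3824 and 2326) and GRIN2D (3611, 4516 and 2763) in every library, and GRIK3 (12767, 21363 and 8663) exceeded GRIK5 (9123, 12110 and 7795).

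Summed AMPA genes reached 246, 312 and 222 TPM in replicates 1, 2 and 3, against 129, 148 and 132 for NMDA genes. Their log2 ratio was 0.92 ± 0.17 and positive in 3 of 3 libraries (exact permutation p = 0.25), but on CPM it was 0.10. Summed kainate genes reached 259 ± 26.6 TPM, and the AMPA to kainate log2 ratio (-0.11, 0.15 and -0.05) did not keep a sign. GRIN2B exceeded GRIN2A by 1.52 ± 0.26 on the log2 scale, and by 3.01 on CPM. GRIA2 was lower than the other 3 AMPA genes together by a log2 ratio of -0.34 ± 0.16 (exact permutation p = 0.25), and without replicate 2 the mean of -0.35 was within 2 SD of 0. All 10 AMPA auxiliary genes were above 1 TPM, with CNIH2 at 409 ± 42.3 TPM and the stargazin relatives CACNG4 at 263 ± 30.4 and CACNG7 at 99.4 ± 2.81. Of 8 metabotropic glutamate receptors 6 were above, led by GRM4 (31.6 ± 1.62 TPM) and GRM7 (27.6 ± 2.33), which lower transmitter release. Of 5 glutamate uptake genes 3 were above, with SLC1A6 at 63.7 ± 11.2 TPM and SLC1A1 at 28.2 ± 4.7 beside SLC1A2.

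Genes of inhibition were expressed as well. Of 19 GABA-A receptor genes 12 were above 1 TPM, led by GABRA3 (212 ± 12.8 TPM) and GABRE (119.9 ± 3.98). Of the alpha subunits that are prominent in the immature brain, GABRA5 was at 23.1 ± 3.65 TPM and GABRA2 at 22.0 ± 6.56. Both GABA-B genes were above, GABBR1 at 266 ± 9.64 TPM and GABBR2 at 60.3 ± 2.88. SLC12A5, the chloride exporter KCC2, was at 136 ± 7.3 TPM and SLC12A2, the importer NKCC1, at 5.66 ± 1.71. The log2 ratio of SLC12A5 over SLC12A2 was 4.6 ± 0.345 (4.69, 4.22 and 4.89; exact permutation p = 0.25) and 3.58 on CPM. Of 4 glycine receptor genes GLRB (68.8 ± 11.5 TPM) and GLRA2 (11.4, 15.4 and 18.2 in replicates 1, 2 and 3) were above, GLRA3 (0.987 ± 0.121) was undecided and GLRA1 (0.203 ± 0.0462) was below.

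**Figure D3:**
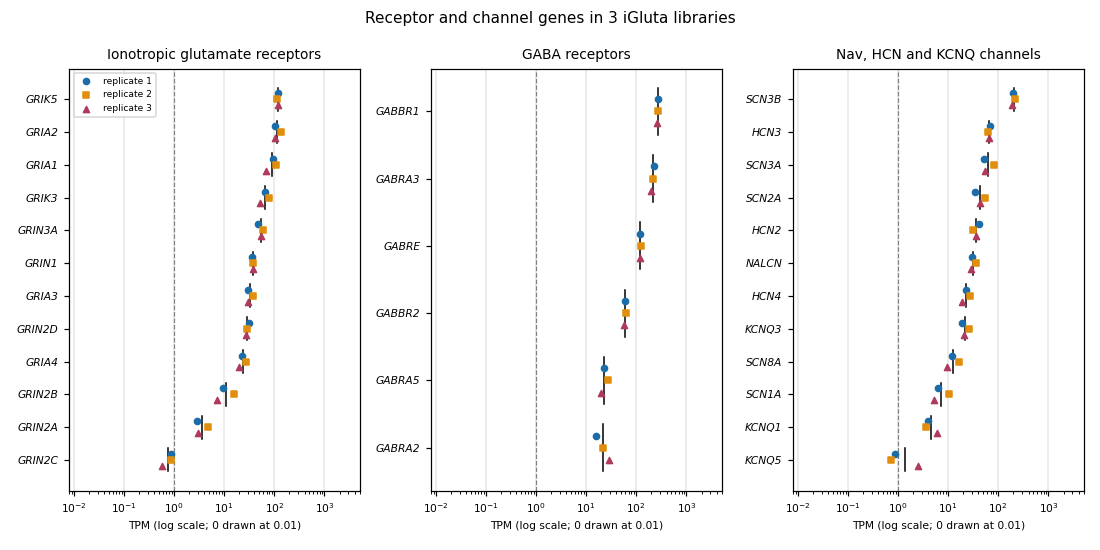
TPM (horizontal log axis, 0 drawn at 0.01) of the named ionotropic glutamate receptor, GABA receptor, and sodium, HCN and KCNQ channel genes in replicates 1 to 3 (circle, square, triangle), with a black tick at the mean and a dashed line at 1 TPM. GABBR1 averages 266 TPM and GABRA3 averages 212 TPM.

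Receptors for acetylcholine, monoamines and other modulators were expressed selectively. Of 13 nicotinic genes 9 were above 1 TPM, led by the partners CHRNA4 (81.7 ± 10.6 TPM) and CHRNB2 (33.8 ± 3.37), with CHRNB1 at 23.8 ± 2.64 and CHRNA7 at 13.9 ± 0.743. CHRNA7 shares most of its exons with the fusion gene CHRFAM7A, so its value is less certain. Of 5 muscarinic genes CHRM2 (22.1 ± 12.2 TPM), CHRM3 (9.25 ± 1.79) and CHRM4 (4.81 ± 0.222) were above, and CHRM1 (0.04 ± 0.0693) and CHRM5 (0.193 ± 0.0503) were below. Of 27 monoamine receptors 12 were above, led by the alpha-2 adrenoceptor ADRA2C (76.6 ± 10.9 TPM), the dopamine D2 receptor DRD2 (70.9 ± 11.3), ADRA2A (15.3 ± 2.33) and ADRA1D (14.5 ± 9.61). CHRM2 was at 12.3, 18.3 and 35.8 TPM and ADRA1D at 8.96, 8.99 and 25.6 in replicates 1, 2 and 3. Of 10 adenosine, cannabinoid and opioid receptor genes 6 were above, with ADORA1 at 45.4 ± 0.701 TPM, the cannabinoid receptor CNR1 at 43.9 ± 13.8, the nociceptin receptor OPRL1 at 26.7 ± 2.75 and ADORA2A at 7.01 ± 3.01, and 3 were above without replicate 2.

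Voltage-gated sodium and calcium channels were broadly expressed. Of 14 sodium channel genes 11 were above 1 TPM, with the beta subunit SCN3B at 202 ± 15.8 TPM, SCN3A at 62.3 ± 15.7, SCN2A at 43.7 ± 10.4 and the leak channel NALCN at 31.4 ± 3.79. SCN3A, which is highest before birth, exceeded SCN1A (7.32 ± 2.76 TPM) by 3.1 ± 0.24 on the log2 scale, and SCN2A exceeded SCN8A (12.5 ± 3.58) by 1.81 ± 0.32, each in 3 of 3 libraries (exact permutation p = 0.25 for both). Of 18 calcium channel genes 15 were above, with the beta subunits CACNB3 (164 ± 12.5 TPM) and CACNB1 (91.7 ± 6.29), CACNA2D2 (53.8 ± 6.57), a target of gabapentinoids, and CACNA1H (43.2 ± 3.7). L-type genes summed to 25.9 ± 5.27 TPM and T-type genes to 71.0 ± 3.17, a log2 ratio of -1.47 ± 0.22 (exact permutation p = 0.25).

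Potassium and HCN channel genes were mostly above the bar. All 20 Kv genes were above 1 TPM, led by KCNH2 (109 ± 7.15 TPM), KCNA6 (36.02 ± 3.95), KCNC1 (33.5 ± 2.67) and KCNC4 (28.6 ± 3.01). Among the HCN genes HCN3 (64.3 ± 2.63 TPM), HCN2 (36.2 ± 4.42) and HCN4 (22.8 ± 3.88) were above. Of the KCNQ genes KCNQ3 (21.7 ± 3.49 TPM) and KCNQ1 (4.5 ± 1.33) were above and KCNQ5 was undecided. Of 9 calcium- and sodium-activated potassium genes 7 were above, led by KCNMA1 (38.0 ± 5.06 TPM) and KCNN1 (31.8 ± 4.81). Of 15 inward-rectifier and leak potassium genes 14 were above, led by KCNK3 (41.1 ± 2.98 TPM) and KCNK9 (30.1 ± 8.31), and 9 were above without replicate 2. Of 9 gap junction genes 5 were above, with PANX1 at 47.3 ± 8.78 TPM and the neuronal connexin GJD2 at 12.6 ± 1.04.

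Activity-regulated and stress genes were expressed. Of 8 activity-regulated genes 6 were above 1 TPM, with FOS at 36.03 ± 2.22 TPM, EGR1 at 21.1, 20.5 and 56.1 in replicates 1, 2 and 3, JUNB at 21.5 ± 5.01 and NR4A1 at 18.6 ± 1.21. All 8 stress genes were above, with the chaperone genes HSPA5 (221 ± 12.8 TPM) and HSPA1A (184 ± 7.83), and CHAC1 (126 ± 40.7) and DDIT3 (97.8 ± 4.57), both targets of the integrated stress response. HSPA1A has a near-identical neighbour, HSPA1B, so the division of reads between them is uncertain.

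Replicate 3 stood apart from the other libraries. Of 11112 protein-coding genes at a mean of at least 5 TPM, 107 were at least 2-fold higher in replicate 3 than in both other libraries, 12 of them mitochondrial, and 58 were at least 2-fold lower. For replicate 1 those counts were 0 and 7, and for replicate 2 they were 10 and 2. In replicate 3 the GABAergic list was lower by a median of -1.04 on the log2 scale (9 of 11 members lower), with SST at 1000.5, 892 and 296 TPM and GAD1 at 203, 234 and 118 TPM in replicates 1, 2 and 3. The dopaminergic list (-0.57, 4 of 5 lower), the glutamate uptake list (-0.56, 4 of 4 lower) and the forebrain list (-0.49, 8 of 11 lower) were also lower there. The progenitor list (1.11, 4 of 5 higher), the epithelial list (0.56, 4 of 4 higher) and the activity-regulated list (0.52, 6 of 7 higher) were higher, as was the mitochondrial mRNA list (1.45, 13 of 13 higher), which was written after the data were examined. The GABAergic median lay below all 10000 random lists matched on expression. The pan-neuronal median differed by -0.05 in replicate 3. These are differences between single libraries and carry no test.

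**Figure D4:**
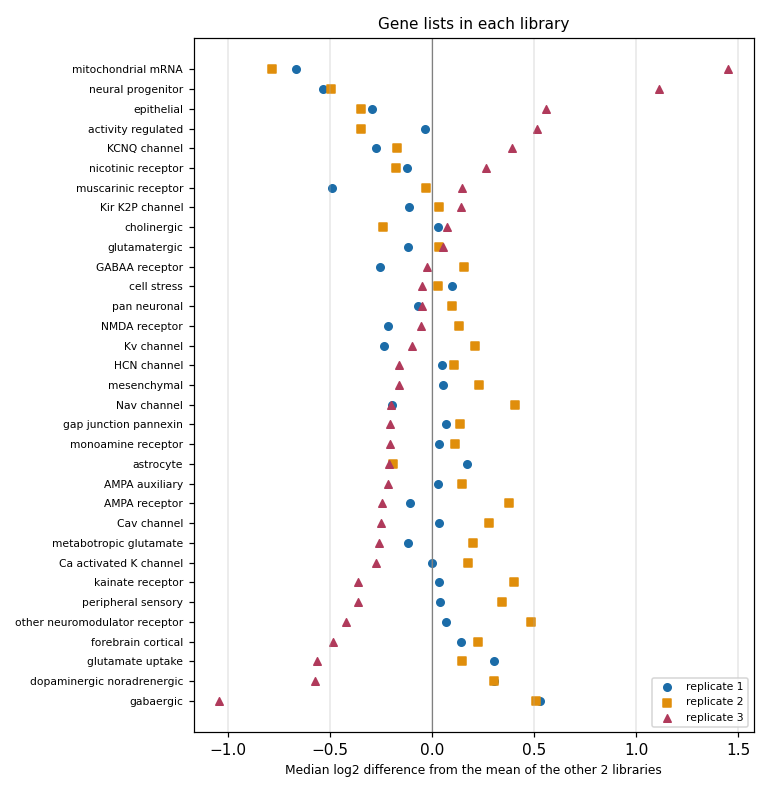
Median log2 difference of gene lists from the mean of the other 2 libraries (horizontal axis), for replicate 1 (circle), replicate 2 (square) and replicate 3 (triangle), over members at a mean of at least 1 TPM. Lists with too few members at that level, and the neuropeptide, ventral forebrain and granin lists, are not drawn. Replicate 3 lies at 1.45 for mitochondrial mRNA and at -1.04 for the GABAergic list.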

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

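All alternatives in this part were fixed before the data were examined. No called ratio changed sign on CPM or with another pseudocount. Leaving out a replicate could not change the sign, since a called ratio has the same sign in all 3 libraries. The number of genes above 1 TPM stayed within 1.5 times of 15837 in all 11 alternatives, from 13945 without replicate 2 to 17711 with a bar of 0.5 TPM. Counts of list members above the bar stayed within 1.5 times in 462 cases and moved further in 22, and all 206 means of the named genes after rescaling by TMM factors lay within 1 SD of the mean reported. The mean of the other libraries always lies within 1 SD when 1 of 3 is left out, so that comparison shows nothing about stability. The cause of the shifts below was not tested, except where the setting itself changes the scale.

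Of the reported log2 ratios 6 moved by at least 1 SD between libraries, all on CPM, which is not divided by gene length. AMPA over NMDA became 0.10, AMPA over kainate -0.17 and DCX over RBFOX3 3.73. GRIN2B over GRIN2A became 3.01, SLC12A5 over SLC12A2 3.58 and SLC17A6 over SLC17A7 3.43. List differences on CPM became 9.76 (pan-neuronal minus astrocyte), -0.26 (glutamatergic minus GABAergic), 7.06 (forebrain minus hindbrain) and 3.94 (forebrain minus peripheral), and 5 progenitor genes were above 1 CPM. Against a bar of 0.5 TPM 5 progenitor and 2 Schwann and neural crest genes were above. Against 2 TPM 2 astrocyte, 3 dopaminergic, 1 mesenchymal, 2 peripheral and 0 Schwann and neural crest genes were above. With list means the forebrain minus hindbrain difference was 5.77, and the glutamatergic minus GABAergic mean of -1.38 lay over 2 SD from 0. With members of a mean count of at least 10 the differences were 7.93 (pan-neuronal minus astrocyte), 0.24 (glutamatergic minus GABAergic) and 3.3 (forebrain minus peripheral). The forebrain minus hindbrain difference was not run there, since no HOX gene was left. A pseudocount of 0.01 made that difference 9.64 and a pseudocount of 1 made it 3.23, while the latter gave 1.99 for forebrain minus peripheral and 7.56 for pan-neuronal minus astrocyte. Without a filter on low counts the coefficient of variation was 0.222, and DESeq2 size factors left it at 0.188.

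Leaving out each replicate in turn gave coefficients of variation from 0.12 to 0.218. The members above the bar ranged from 9 to 13 for inward-rectifier and leak potassium channels, 2 to 3 for astrocyte, 3 to 5 for dopaminergic, 2 to 3 for mesenchymal, 3 to 5 for other neuromodulator receptor, 2 to 3 for peripheral, 1 to 2 for proliferation and 0 to 1 for Schwann and neural crest genes. Fewer libraries widen the error of the limma fit. No paired analysis was possible because the series has 1 group. With 34732725 to 60092991 counts per library, depth limits only genes near the floor of 3 counts.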

Other observations

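The gene lists in this part and the tests on the share of GABAergic neurons, on mitochondrial DNA and on astrocytes were chosen after the result was seen, and so were the genes named here. The tests on mitochondrial crowding and on GC content and length were written before their results.

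Some neuropeptide genes were abundant, although the list median was 7.46 TPM. The share of the list above the bar was near that of all protein-coding genes (12668 of 20116). Of 28 precursor genes 19 were above 1 TPM (limma), led by SST (729.7 ± 379 TPM, n = 3 here and below), GHRH (198 ± 28.8), which releases growth hormone, GRP (172.6, 154 and 176 in replicates 1, 2 and 3), TRH (165 ± 13.0), which acts on the pituitary, PDYN (111 ± 76.3), NTS (92.3 ± 34.1), the enkephalin precursor PENK (82.5 ± 39.1) and PNOC (63.0 ± 20.4). PDYN was at 65.1, 69.0 and 199 TPM and PENK at 111, 98.6 and 37.9 in replicates 1, 2 and 3, so the opioid precursors moved apart. All 6 granin genes of dense-core vesicles were above, with VGF at 1331 ± 188 TPM and SCG2 at 1057 ± 228. POMC, AVP and OXT were below the bar.

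Transcription factors of the ventral forebrain were expressed beside the cortical ones. Of 12 such genes 9 were above 1 TPM, among them PBX3 (116 ± 29.3 TPM), MEIS2 (81.7 ± 28.9), SIX3 (57.5 ± 19.7) and SP8 (30.7 ± 10.5). DLX1 (66.7 ± 25.1 TPM) and DLX5 (50.9 ± 20.4), of GABAergic progenitors and interneurons, were also above, as was NKX2-1 at a lower level (2.56 ± 0.0721), and LHX6 was undecided (0.487 ± 0.308). The cortical excitatory factors NEUROD2 (0.02 ± 0.02) and NEUROD1 (0.0767 ± 0.0306) were below, and NEUROD6 was listed at 0. In replicate 3 the ventral list was lower by a median of -0.99 on the log2 scale (8 of 9 lower).

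The GABAergic list was lower in replicate 3. It kept a median of -0.94 (from -1.04) with mitochondrial genes left out and TPM rescaled, and -1.0 after a fit on GC content and transcript length, which explained 1.5% of the variance, so neither accounts for it. Whether a lower share of GABAergic neurons was the only difference was not decided. It would lower all 11 members, and CALB2 was instead 0.72 higher there (0.08 between replicates 1 and 2), but other neurons can also express it. Glutamatergic and cholinergic genes would rise alike. They spanned 1.54 instead, from CAMKV (-0.34) to SLC5A7 (1.2), against at most 0.49 between replicates 1 and 2. Which cells express these genes was not measured, so neither result decides against a lower share. GAD1, GAD2, SLC32A1 and DLX1, DLX2, DLX5 and DLX6 lay within 0.31 of each other, at 0.44 to 0.54 of the other libraries, as a lower share would give; this 7-gene test was replaced by the test on all 11 members after its result was seen. A lower share stays open as a hypothesis, and replicate 3 also differed in other genes. The libraries hold RNA pooled from all cells, so they cannot tell fewer GABAergic neurons from lower expression of GABAergic genes within the same cells. Nor do they show that these transcripts came from separate GABAergic neurons. The design names no biological difference between the samples.

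Mitochondrial transcripts were higher in replicate 3. DNA carried into the library as the only source would add alike to all mitochondrial genes. The highest TPM gain (MT-ATP8, 11850) was instead 11.8 times the lowest (MT-RNR1). MT-ATP8 is a very short transcript, so its TPM is uncertain. With MT-ATP8 set aside, MT-CO2 gained 7859 against 1001 for MT-RNR1 and 1273 for MT-ND1. These gains argue against DNA as the only source, and they cannot exclude DNA added to a rise in RNA. The mRNAs kept a median of 1.61 (from 1.45) after the fit on GC content and length. RNA quality and the state of the cells stay open, since neither was tested. In replicate 3 the activity-regulated list was higher by a median of 0.52 (6 of 7 higher), and the stress genes went both ways (3 higher and 5 lower), which does not decide the cause. No biological explanation was tested. POSTN (0.12, 0.42 and 19.98 TPM), ID3 (2.19, 2.51 and 51.8) and TNFRSF12A (11.5, 11.2 and 127) were among the nuclear genes farthest above the other libraries in replicate 3, and CRH (13.2, 10.6 and 1.89) and GAL (58.9, 51.4 and 15.9) were among those farthest below.

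SLC1A2 and ALDOC stood far above the other genes of the astrocyte list. SLC1A2 exceeded the highest of GFAP, AQP4, GJA1 and ALDH1L1 by at least 49.6 times in every library. Astrocytes would bring all their abundant transcripts, so they are argued against as the main source of SLC1A2, and a small number of them is not excluded. Expression of both genes by the neurons stays open and was not tested, and no biological explanation was tested against another group.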
